A study of Mus musculus with 6 samples.

How the data were processed

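The labels describe 2 kinds of material. The first is a chromatin immunoprecipitation sequencing (ChIP-seq) experiment with 1 library per antibody in BM-HPC cells, a hematopoietic progenitor/stem cell line from mouse bone marrow. The second is a set of 4 flow-sorted bone marrow samples (the LSK population, from mice with or without Cbp), which list no processed file and were not analysed here. Per the labels' protocols, BM-HPC cells were crosslinked with 1% formaldehyde, lysed and precipitated with a rabbit polyclonal antibody against Cbp or with rabbit IgG, the non-specific control.

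Each library was deposited as a list of genomic intervals, 1 line per read, on genome build mm9 per the submitters' processing notes. The deposited intervals hold a chromosome, a start and an end, with no strand, score or sequence. Of the intervals, all but 23 in the Cbp file and all but 51 in the IgG file were exactly 200 bp long, which is how reads extended to a fixed fragment length look. The aligner, the mapping filters and the extension step are not given in the sources used here. The Cbp sample also has a deposited list of 4012 peaks, each 400 bp wide and again without score, height or p-value. The peak caller, its threshold and whether the control entered the calling are not given in the sources used here. Each library came from a single sample, so nothing was pooled.

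The value computed from these files was the number of interval midpoints per region, which stands for the fragment centre. Intervals with the same chromosome, start and end were counted as duplicates and 1 was kept. Since the strand is not in the files, 2 reads from opposite strands that extend to the same interval cannot be told from a duplicate. Mitochondrial reads were left out of nuclear totals. This left 9388703 Cbp and 6886428 IgG nuclear reads, so that a region with no read is compatible with up to 3 reads, or 3.20e-05% of the Cbp library and 4.36e-05% of the IgG library. RPM values are reads scaled to these totals. Libraries were scaled by their non-duplicate reads outside the deposited peaks, which gave 1.36 Cbp reads per IgG read.

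Per region, Cbp and IgG counts were compared with an exact conditional binomial test, two-sided, and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The regions were the 4012 rows of the peak list, and separately all 1 kb windows of the genome with 10 or more reads over both libraries. Ratios have exact 95% intervals, and shares have exact Clopper-Pearson 95% intervals. Because each antibody has 1 library, these tests and intervals compare the libraries and cover counting error only. They contain no variation between cultures or precipitations. The peak list belongs to the same Cbp sample, so counts inside it are not independent evidence. Peak numbers per chromosome were compared with an even spread by a chi-square statistic over 10000 simulated placements. Overlap between peaks and windows needed 1 bp and was set beside 100 shuffles of the peaks within their chromosomes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

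The test was tested on simulated data, drawn from the real regions' summed counts with 100 regions raised 4-fold and 100 raised 8-fold. Over the 4012 peak rows it recovered 71% of the 4-fold and 100% of the 8-fold changes with 5 false calls, over both directions, among 176. Over 566385 simulated 1 kb windows it recovered 9% and 86%, with 0 false calls among 95, so the window test has little power for moderate enrichment. For rows and windows alike the changes were added on top of the real counts. Raised regions therefore held more reads than real regions of the same fold. The recovered shares, also those over the peak rows, thus overstate the power at the read counts of real regions.

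The design, the alternatives and the rule for the regions named were fixed before the data were examined. The rule named the 10 peaks with the largest excess of Cbp over IgG reads, scaled to library depth, among those past the threshold, the 5 most extreme windows outside peaks in each direction, and the chromosomes with the highest and lowest density of peaks. Alternatives were keeping duplicates, other scalings, 500 bp windows, no minimum count, a threshold of 0.01, the 2006 rows with most Cbp reads and keeping mitochondrial reads. Results planned for promoters, fixed gene lists and sequence motifs needed a genome and gene annotation of build mm9, which were not used here, and regions are therefore given by position without gene names. Where rows of the peak list share 1 bp or more they were also merged into distinct regions, a step added after the data were seen.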

Results

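The ChIP-seq experiment asked where Cbp sits on the genome of BM-HPC cells. Cbp (CREB-binding protein, encoded by Crebbp) is a transcriptional co-activator with lysine acetyltransferase activity that is recruited to DNA by transcription factors. BM-HPC is a mouse bone marrow line of hematopoietic progenitor and stem cells and was grown with 100 ng/ml stem cell factor and 10 ng/ml IL-6, without treatment. One library was made with an antibody against Cbp and 1 with rabbit IgG. The Cbp library held 9770169 reads, of which 3.88% were duplicates. The IgG library held 8068592 reads, of which 14.6% were duplicates. There were no replicates, so all intervals below are exact 95% intervals for counting error, and all tests compare the 2 libraries and not the conditions behind them.

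The peak list consisted of 3 consecutive runs, each ordered by chromosome from the start, with 2422, 806 and 784 rows. The later runs described the same places: all 806 rows of the second run shared sequence with a row of the last run, at a median offset of 30 bp, and all 784 rows of the last run shared sequence with the second. Only 6 rows of the first run overlapped the second run, and 0 overlapped the last. Merging rows that share 1 bp or more left 3014 distinct regions over 1320979 bp, of which 2380 came from the first run alone, 628 from the later runs and 6 from both. The 4012 rows therefore exceed the number of separate places by 998.

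In summed non-duplicate reads the first run held more Cbp than IgG, while the later runs held about equal shares. The list belongs to this same Cbp sample, so an excess of Cbp inside it can come in part from the choice of rows and is given as a description. First-run regions held 0.297% (0.293 to 0.300) of the Cbp reads and 0.103% (0.100 to 0.105) of the IgG reads, a ratio of 2.89 (2.82 to 2.97). Second-run regions held 0.190% (0.187 to 0.193) of the Cbp reads and 0.194% (0.190 to 0.197) of the IgG reads, a ratio of 0.982 (0.960 to 1.00). For the last run the ratio was 0.950 (0.929 to 0.972). Over the whole list 0.503% (0.498 to 0.508) of Cbp reads and 0.314% (0.310 to 0.318) of IgG reads fell in peaks, a ratio of 1.60 (1.58 to 1.63). With duplicates kept this ratio became 0.871 (0.864 to 0.877), which turns its direction, while that of the first run was 2.8 (2.73 to 2.87). The later runs then stood at 0.759 (0.753 to 0.765) and 0.740 (0.734 to 0.746). The median first-run row held 10 Cbp reads (quartiles 8 and 12) and 2 IgG reads (quartiles 1 and 3). The median second-run row held 15 Cbp and 9 IgG reads. Of the second-run rows 37.1%, and of the last-run rows 40.8%, lay at or below the expected Cbp share. Most rows of the later runs thus leaned to Cbp, although their sums did not.

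**Figure D1:**
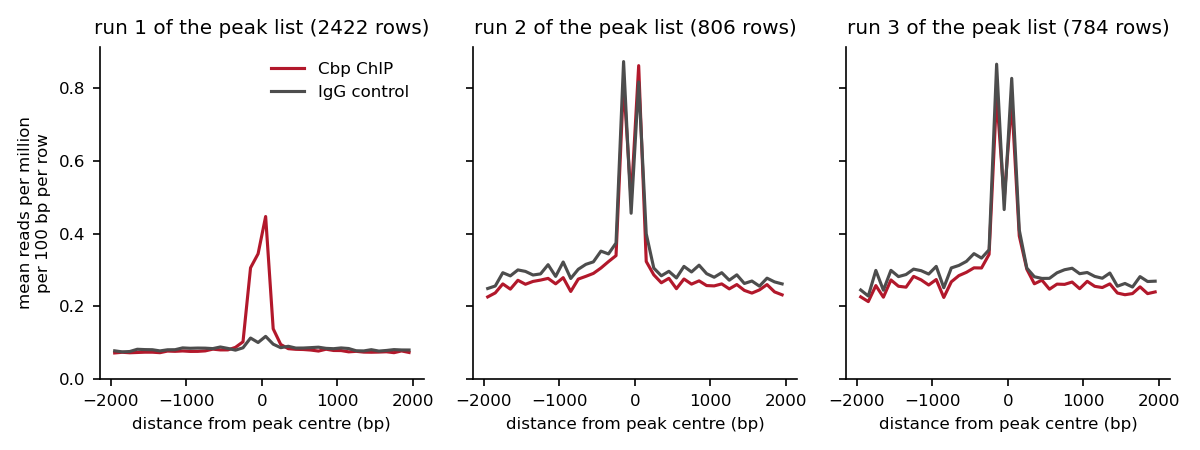
Mean non-duplicate reads per 100 bp and row in RPM (reads scaled to library depth) (vertical axis) against the distance from the peak centre in bp (horizontal axis), for the 3 runs of the peak list, with the Cbp library in red and the IgG library in grey. Within 100 bp of the centre of first-run rows Cbp reached 0.448 RPM and IgG 0.118 RPM, while in the later runs the lines of both libraries run close together.

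Of the 4012 rows, 341 (8.50%) had more Cbp than IgG reads by the exact binomial test, 64 had more IgG reads and 3607 did not pass. At an unadjusted p below 0.05 these numbers were 1032 and 99. The first run held 285 of the Cbp-higher rows, and each later run 28. Each later run also held 28 IgG-higher rows, and the first run 8. Among distinct regions 342 were Cbp-higher and 38 IgG-higher. The 19 IgG-higher regions on chromosome 11 held 284 Cbp and 1048 IgG reads in sum. By contrast, the 8 on chromosome 9 held 1356 and 1411, and the 4 on chromosome 2 held 561 and 608. Where a region is full of reads, counting each interval once makes both counts alike. Scaled by 1.36, near-equal counts then give an IgG-higher call that need not show an excess of IgG. Of the 2380 regions from the first run alone 309 were Cbp-higher, against 33 of the 628 from the later runs (two-sided Fisher's exact test on regions, p = 7.45e-09, odds ratio 2.69). How each run was chosen is not given, and the median region held 2 IgG reads in the first set and 10 in the other. The test also treats neighbouring regions as independent, so it describes this list and is no evidence of binding. The Cbp-higher regions held 11 to 62 Cbp reads, with a median of 17 Cbp and 1 IgG read. In 127 of them the IgG library had no read. At a threshold of 0.01 the number of Cbp-higher rows dropped to 95, and with duplicates kept it was 668.

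**Figure D2:**
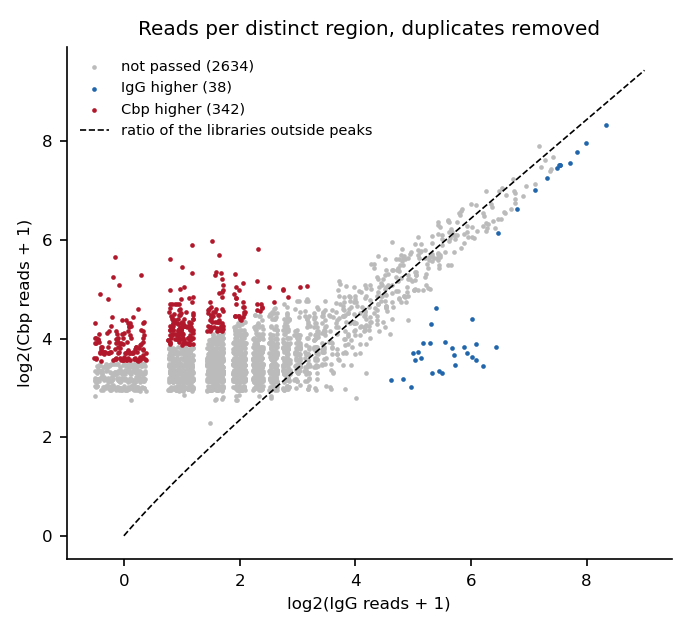
Cbp reads (vertical axis) against IgG reads (horizontal axis) in each of the 3014 distinct regions, both as log2(reads + 1) after removal of duplicates, with a small random shift so that equal counts can be seen. The dashed line is the ratio of the libraries outside peaks, the 342 Cbp-higher regions (red) lie at low IgG counts, and 38 regions (blue) lie below the line.

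The 10 peaks with the largest excess of Cbp reads all belonged to the first run. The largest excess lay on chromosome 1 at 88330943 to 88331342, with 62 Cbp and 2 IgG reads, a 22.8-fold difference (6.05 to 192, adjusted p = 4.03e-10, exact binomial test). The peak on chromosome 8 at 86590559 to 86590958 held 59 Cbp reads and 1 IgG read, a 43.4-fold difference (7.49 to 1741, adjusted p = 1.59e-10, exact binomial test). On chromosome 9 at 20455938 to 20456337 there were 55 Cbp and 4 IgG reads, a 10.1-fold difference (3.73 to 38.4). The peak on chromosome 19 at 4282981 to 4283380 held 49 Cbp reads and no IgG read. Set against a floor of 3 IgG reads this is 12-fold higher in Cbp, a value that leaves out counting error in the Cbp reads. On chromosome 2 a peak at 134469781 to 134470180 held 51 Cbp and 2 IgG reads, and a second at 30513904 to 30514303 held 39 and 1. Chromosome 13 at 91600504 to 91600903 held 48 Cbp reads and 1 IgG read, a 35.3-fold difference (6.04 to 1422). Chromosome 1 at 174444030 to 174444429 held 43 Cbp reads and 1 IgG read. Chromosome 5 at 115750947 to 115751346 held 38 Cbp reads and no IgG read, 9.31-fold higher against the same floor. Chromosome 9 at 45820555 to 45820954 held 40 Cbp and 2 IgG reads. The adjusted p of these 10 peaks was at most 9.37e-06 (exact binomial test).

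The rows with most reads, chosen after their values were seen, were also full of reads in the control. On chromosome 2 at 98502717 to 98503116 the Cbp library had 35694 reads and the IgG library 42152, which fell to 322 distinct intervals in each, a scaled ratio of 0.735 (0.628 to 0.860). On chromosome 9 at 35112824 to 35113223 there were 15294 Cbp and 18264 IgG reads (ratio of distinct intervals 0.726, 0.607 to 0.868). A row on chromosome X at 139917399 to 139917798 held 4843 Cbp and 4080 IgG reads (ratio 0.706, 0.530 to 0.941). Its distinct intervals numbered 98 in Cbp and 102 in IgG, and those of the chromosome 9 row 250 and 253. With each interval counted once, such full rows reach near-equal counts, and scaling by 1.36 then sets a ratio near 0.735. These ratios and their intervals therefore do not measure an excess of IgG. With duplicates kept, the 5 regions with most Cbp reads took 49.4% of all Cbp reads in peaks and 59.7% of all IgG reads in peaks.

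A plain window count, which uses no peak position, called few places with an excess of Cbp. Of 480001 windows of 1 kb with 10 or more reads, 14 were Cbp-higher and 27 IgG-higher by the exact binomial test, against 6871 and 10995 at an unadjusted p below 0.05. All 14 Cbp-higher windows overlapped a row of the list. The lowest p belonged to windows of the first 2 peaks named above, on chromosomes 1 and 8. Each held 66 Cbp and 3 IgG reads (16.2-fold, 5.30 to 80.4, adjusted p = 6.57e-08, exact binomial test). Folds were higher on chromosome 13 at 91600001 to 91601000 (38.2, 6.56 to 1538) and on chromosome 1 at 154750001 to 154751000 (22.1, 3.67 to 899), on fewer reads. These windows touched 14 of the 4012 rows (0.349%), while 100 shuffles of the rows gave at most 1 (permutation p = 0.0099, one-sided, the smallest the shuffles can give). Windows and list come from the same Cbp sample, so such an overlap was to be expected from shared reads and is not independent evidence for the list. The median tested window held 11 reads over both libraries. In simulated data, where changes were added on top of such counts, the test recovered only 9% of 4-fold changes. With 500 bp windows the counts were 36 and 44.

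Of the 27 IgG-higher windows 19 lay in a stretch of 110 kb on chromosome 11 that starts at 100640001, where the IgG library had 1719 reads and the Cbp library 836, a ratio of 0.357 (0.329 to 0.388). Outside peaks the most extreme IgG-higher window lay on chromosome 17 at 4626001 to 4627000, with 92 IgG and 10 Cbp reads, a Cbp-to-IgG ratio of 0.0799 (0.0371 to 0.154, adjusted p = 4.29e-18, exact binomial test). Others were on chromosome 11 at 100740001 to 100741000 (51 IgG and 9 Cbp reads), on chromosome 2 at 16604001 to 16605000 (46 and 9), on chromosome 14 at 104736001 to 104737000 (42 and 7) and on chromosome 11 at 25000001 to 25001000 (32 and 4). Mitochondrial reads were also rarer in the Cbp library, at 0.0337% (0.0325 to 0.0348) against 0.109% (0.107 to 0.112) in IgG.

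**Figure D3:**
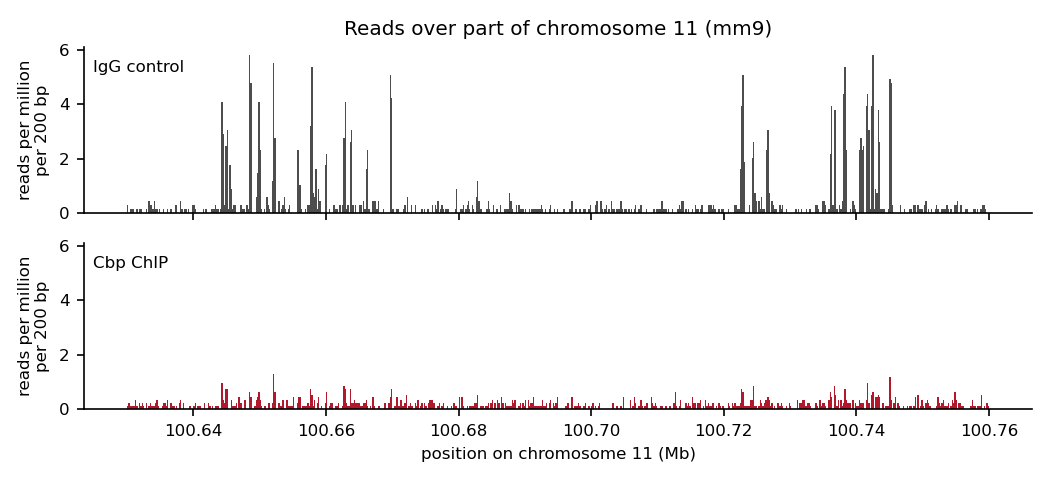
Non-duplicate reads per 200 bp in RPM (vertical axes) along part of chromosome 11 in Mb of mm9 (horizontal axis), for the IgG library (top, grey) and the Cbp library (bottom, red) on the same scale. The IgG library has sharp stacks in 2 groups, from 100644301 to 100683000 and from 100722501 to 100745400, and the Cbp library has lower ones there.

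Peaks were unevenly spread over the chromosomes. Chromosome 1 held 870 of the 4012 rows, or 4.48 per Mb (4.19 to 4.79), against 1.55 per Mb over all chromosomes. This is 2.88 times (2.69 to 3.08) the number expected from length. Rows are not independent, since the later runs list the same places, so these intervals are too narrow. Of the 3014 distinct regions 616 lay on chromosome 1, 2.72 times (2.51 to 2.94) the number expected from length. Against the number expected from IgG reads, the excess was 2.05 times (1.87 to 2.24) for first-run regions and 1.70 times (1.54 to 1.86) for regions outside 1 Mb windows that held 10 or more of them. An expectation in proportion to reads does not remove the effect of depth on places chosen by read counts. Of 400 bp windows with 8 or more IgG and 2 or fewer Cbp reads, 20.6% lay on chromosome 1, which held 9.94% of IgG reads. The excess therefore need not go beyond depth. Chromosome 11 was next with 2.73 per Mb (2.44 to 3.05). Chromosome X had the lowest density, 0.617 per Mb (0.503 to 0.750), and chromosome 14 had 0.679 per Mb (0.541 to 0.842). The chi-square statistic of rows against an even spread was 1573 (p = 1e-04 from 10000 simulated placements, one-sided, the smallest they can give). For distinct regions it was 940, and the placements treat rows or regions as independent. Part of the rows lay in tight groups, which were looked for after the data were seen: 20 windows of 1 Mb with 10 or more regions each held 498 (16.5%) of the distinct regions. The richest were chromosome 1 at 90108517 to 90591484 with 79 regions, the start of chromosome 11 at 3000268 to 3795349 with 62, chromosome 1 at 85071641 to 85342192 with 49 and the start of chromosome 9 at 3000451 to 3259069 with 37. Regions inside these 20 windows had a summed Cbp-to-IgG ratio of 0.981 (0.956 to 1.01), and 13 of them were Cbp-higher. That ratio was 1.07 (1.04 to 1.10) without the window on chromosome 11 that holds the IgG stacks, 1.06 (1.03 to 1.09) without the one at the start of chromosome 9, and 1.20 (1.16 to 1.23) without both. Taken singly, 14 of the 20 windows had an interval above 1, 2 below 1 and 4 that included 1. Of the 2 below 1, the window at the start of chromosome 9 held 2398 Cbp and 2413 IgG reads, a ratio of 0.730. Such near-equal counts can come from counting each interval once, so this ratio need not show an excess of IgG. The 2516 regions outside had a ratio of 2.13 (2.08 to 2.17), and 329 were Cbp-higher.

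Among first-run regions, the Cbp-higher ones lay on chromosome 1 less often than the others. The tests per chromosome compare the Cbp-higher regions with IgG reads and not with the list. Chromosome 8 held 32 of the 342 where its IgG reads predicted 16.5, a ratio of 1.94 (1.33 to 2.74, adjusted p = 0.00376 over 21 chromosomes, two-sided exact binomial test). Chromosome X held 3 where 16.5 were predicted, a ratio of 0.182 (0.0375 to 0.532, adjusted p = 0.00236, exact binomial test). It also had the lowest density in the whole list, so a deficit there is shared with the list. Chromosome 1 held 36 where 34.0 were predicted (1.06, 0.741 to 1.47, adjusted p = 0.793, exact binomial test), and no chromosome other than 8 and X passed. Among first-run regions, 9.71% of the Cbp-higher and 22.0% of the others lay on chromosome 1 (two-sided Fisher's exact test, p = 1.34e-07, odds ratio 0.382). The others include all regions with too few Cbp reads to pass. Read depth on chromosome 1 itself stood apart in both libraries. Its median count per 10 kb was 1.36 times that of the other autosomes in the Cbp library and 1.31 times in the IgG library, while the 18 other autosomes ranged from 0.944 to 1.11 and from 0.923 to 1.12. Chromosome X was at 0.833 and 0.846. No Cbp-higher region held fewer than 11 Cbp reads, which are harder to reach at lower depth. An expectation in proportion to IgG reads does not cover this.

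**Figure D4:**
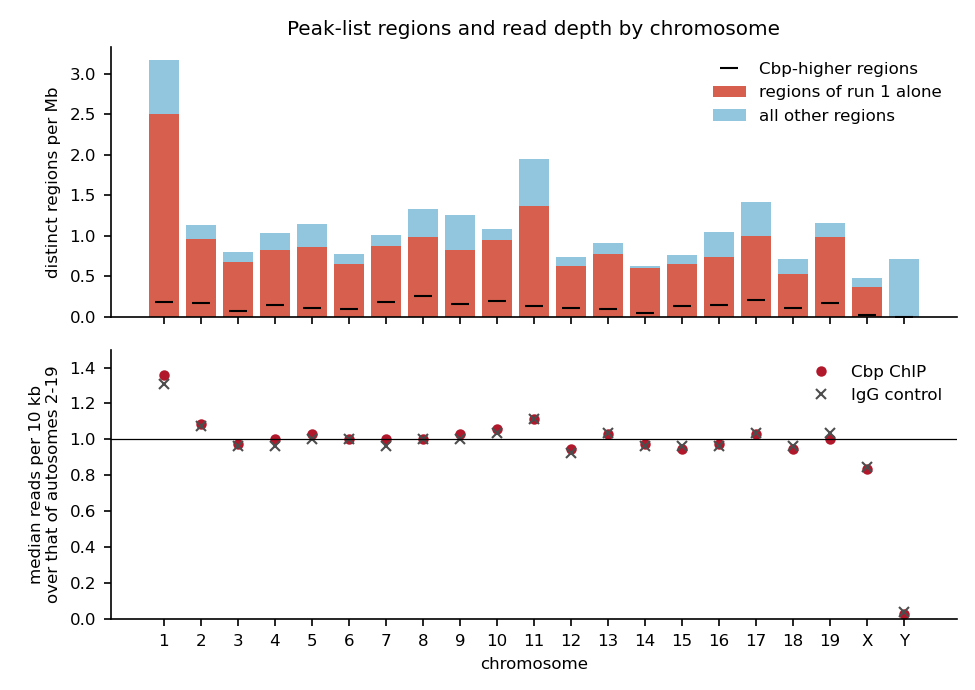
Top, distinct regions of the peak list per Mb on each chromosome, as bars stacked by origin (first run alone, all other regions), with dashes for Cbp-higher regions. Bottom, median non-duplicate reads per 10 kb on each chromosome divided by the median over the autosomes other than chromosome 1, for Cbp (red points) and IgG (grey crosses), where chromosome 1 reaches 1.36 and 1.31.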

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

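The comparisons of single runs of the list, of merged rows, of regions without dense 1 Mb windows and of counts expected from IgG reads were chosen after the data were seen. The Cbp-to-IgG ratio of read shares in the peak list (1.60) depended on duplicates and on which part of the list was used. It turned to 0.871 when all deposited reads were kept, was 1.40 over the 2006 rows with most Cbp reads, and was 2.89 for the first run of the list, 0.982 (0.960 to 1.00) for the second and 0.950 for the last. Stacks of identical intervals make the turn with all reads kept, since nothing else differs in that setting. The count of 341 Cbp-higher rows became 668 with all reads kept and 95 at a threshold of 0.01, and was 44 when the rows of the later runs were tested and adjusted by themselves. The whole-genome and 10 kb window scalings left it at 341, and merging overlapping rows, the first run alone, removing the dense 1 Mb windows and the rows with most Cbp reads, each adjusted anew, gave 309 to 398. Of 1 kb windows, 14 were Cbp-higher and 27 IgG-higher, which became 33 and 114 with all reads kept, 36 and 44 with windows of 500 bp, and 8 Cbp-higher both without a minimum count and at a threshold of 0.01. The share of rows touched by a Cbp-higher window (0.349%) was 0.823% with all reads kept and 0.997% with 500 bp windows, where the cause was not tested, and 0.698% for the rows with most Cbp reads, which is 14 touched rows again, among 2006. The chi-square statistic of the spread over chromosomes (1573) was 1141 for the rows with most Cbp reads, 1639.5 against windows that hold a read, 940 with rows merged and 212 for first-run regions outside dense windows expected from IgG reads, on fewer regions in all but the windows that hold a read. Its permutation p was in each case the smallest the simulations can give (1e-04), which does not show how much of the spread was lost. Fragment shifts were not run because reads were deposited without strand, at a fixed length that looks already extended. The planned results on promoters, gene lists and motifs, with their alternatives, were not run because no genome of build mm9 was used. No paired analysis was possible because each antibody has 1 library and the LSK samples were not analysed here. Depth limits the rest: the median first-run row rested on 10 Cbp and 2 IgG reads.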

Other observations

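The tests in this part were chosen after the result was seen, except the one on the spacing of Cbp-higher regions, and for the chromosome 11 clusters, the depth of chromosome 1 and the flanks of first-run rows the deciding bounds were also reset after values were seen.

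The control library held a set of sharp read clusters on chromosome 11 that the Cbp library showed at a much lower level. Between 100644301 and 100745400, 43 segments built from 100 bp bins with 5 or more IgG reads covered 8% of a stretch of 110 kb that starts at 100640001 and held 72.8% of the IgG reads there, against 30.5% of the Cbp reads. They formed a first group up to 100683000 with 598 IgG and 130 Cbp reads and a second from 100722501 with 654 IgG and 125 Cbp reads. The deposited Cbp peak list has 31 rows in this interval.

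Extra genomic copies of the interval would raise the stretches between the segments as much, but these stood at 1.35 (1.21 to 1.5) times the rest of chromosome 11 in IgG while the whole stretch stood at 4.96 (4.73 to 5.21) times. The stretches between were 1 kb windows chosen for having no bin with 5 or more IgG reads, which by itself lowers their IgG count. Cbp reads, which had no part in that choice, stood at 5.753 per kb there and 4.225 per kb on the rest of the chromosome. Repeated copies of few molecules are argued against as the whole cause because this 4.96 counts each interval once, although 27.8% of the IgG reads in the dense bins were duplicates, against 14.6% in the whole IgG library and 3.04% of the Cbp reads in these bins. DNA from outside the chromatin, such as a cloned or amplified product that carries short pieces of this interval, stays open as a candidate explanation: 1 kb windows with a dense bin stood at 3.02 (2.72 to 3.34) times the rest of the chromosome in Cbp, but their choice from IgG reads fixes a smaller Cbp excess, which therefore decides nothing. Between the segments the libraries did not differ by more than counting error (Cbp-to-IgG ratio 0.996, 0.864 to 1.15). No biological explanation was tested because the design names none.

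Chromosome 1 was read more deeply than any other autosome in both libraries. Enrichment by the antibody is argued against because the IgG library alone stood at 1.31, where its highest other autosome reached 1.12, although the Cbp-to-IgG ratio of the depth, 1.04, was as high on another autosome (1.04) and by itself decided nothing. A few heavy stacks of reads are argued against because the 10th percentile of 10 kb windows was raised as well, 1.43 times in IgG, where the highest other autosome reached 1.21. Extra copies of chromosome 1 in the cultured line are a hypothesis that these values are consistent with: 95% of its 10 Mb segments (19 of 20) exceeded the autosome median in IgG, against 45.3% on the other autosomes, with single segments from 1 to 1.65 times that median. Base composition and mappability cannot be told apart from this without a genome sequence, although the IgG ratio differed by 0.121 at most among 5 percentiles of the windows.

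Part of the first-run rows that were not Cbp-higher may be chance clusters of reads. Among distinct regions this class holds all with 10 or fewer Cbp reads, which could not pass, so it does not stand for absence of enrichment. With the Cbp library thinned to 6886428 reads, 1505 windows of 400 bp had 8 or more Cbp and 2 or fewer IgG reads, and 1718 had the mirrored pattern, a ratio of 0.876 (0.817 to 0.939). At this bound the counts thus leaned to IgG, so the mirrored pattern is no exact measure of chance. Above it they leaned to Cbp. At 10 or more reads the counts were 346 and 173, a ratio of 2 (1.66 to 2.42). The ratio was 4.57 (3.19 to 6.71) at 12, 2.94 (1.70 to 5.34) at 15 and 2.71 (1.09 to 7.64) at 20. These bounds count Cbp reads after thinning, so they are not on the scale of the Cbp counts given for first-run rows. Chance clusters should gather where depth is high. Of first-run regions that were not Cbp-higher, 22.0% (20.2 to 23.8) lay on chromosome 1, beside 20.6% (18.7 to 22.5) of the windows chosen for high IgG. Windows chosen for high Cbp gave 20.7% (18.6 to 22.8), and the Cbp-higher regions 9.71% (6.65 to 13.6). Outside the dense 1 Mb windows, 19.45% of first-run regions that were not Cbp-higher and 8.39% of the Cbp-higher lay there. Weak real sites picked by a read count would gather there too, so these shares cannot separate them from chance clusters. Reads 300 to 1000 bp from the centre had a Cbp-to-IgG ratio of 0.923 for rows that were not Cbp-higher and 0.955 around matched windows outside peaks, which was first read as fitting chance clusters, but Cbp-higher rows had no higher flanks either (0.877), so this test decides nothing.

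A last hypothesis, that Cbp-higher regions lie closer to each other than other regions of the list, was not borne out over the whole list. Of 342 regions 36 had a Cbp-higher neighbour within 100 kb, where 1000 draws of as many regions from the same chromosomes gave 60.7 on average, a number that the dense 1 Mb windows raise. Outside the dense 1 Mb windows the counts were 30 of 329 and 28.2 on average (permutation p = 0.42, one-sided), which leaves the question open there.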
